A study of Mus musculus with 9 samples.

How the data were processed

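Satellite cells of C57Bl6 mice were sampled freshly isolated, proliferating and as myotubes, with 3 independent samples from different animals per stage, per GEO's sample labels. Per the submitters' processing notes, 100 ng of total RNA per sample was depleted of ribosomal RNA with RiboGone, and libraries were made with the SMARTer Stranded Total RNA kit. Reads were aligned to mm10 (GRCm38) with STAR 2.4.0a and counted per gene with featureCounts 1.4.5-p1 of the Subread package, per the same notes. The strand setting of the counting is not given, so values of overlapping or antisense genes are uncertain, as are those of near-identical gene copies.

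The file analysed here is the gene table as deposited by the authors, with 45706 genes and 9 libraries. Its score values are gene read counts that the authors had scaled between libraries and rounded to whole numbers before deposition, and the tool of that normalization is not given in the sources used here. The values of the low genes in each library fall on multiples of 1 step. That step put 1 read at 0.748 to 2.18 normalized units, and the reads per library were estimated from it. The 3 columns with the prefix Q were taken as the freshly isolated libraries by elimination, because the other 2 prefixes match the proliferating and differentiated stages.

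Gene symbols and types come from the deposited table, and positions from GENCODE vM21, to which 45143 genes matched. Of all genes 13802 were 0 in all libraries. The 37 genes of mitochondrial DNA, including 13 protein genes, were listed at 0 in all 9 libraries.

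Genes at 10 or more in at least 3 libraries were kept, 17291 in all. Tests on counts, which the design had foreseen, were not used because the values are scaled and rounded. Values were put on the log2(value + 1) scale without further scaling, and the 3 stages were compared in 1 limma model with a mean-variance trend, using all 9 libraries. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 over all genes tested. Gene lists were tested with camera at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of each comparison, and again with the correlation estimated per list. Lists with fewer than 3 tested genes (erythroid, adipocyte) were counted and not tested. The lists were satellite cell quiescence, Notch pathway, immediate early and dissociation stress, myogenic transcription factors, mitotic cell cycle, DNA replication, cell cycle inhibitors, sarcomere, excitation-contraction coupling, neuromuscular junction, myoblast fusion, glycolysis and phosphocreatine, oxidative phosphorylation and TCA cycle, fatty acid oxidation, ribosome biogenesis, extracellular matrix, chromatin and DNA methylation enzymes, imprinted genes, FGF and HGF signalling, interferon response, and markers of endothelial, leukocyte, fibro-adipogenic or fibroblast, pericyte or smooth muscle, Schwann, erythroid, tenocyte, adipocyte and adult myofibre cells. Each listed symbol but 1, Zac1, was found in the table. The model, the filter, the threshold, the lists and most of the alternative fits were chosen before the data were examined. A simulation set 100 genes each to a 2-fold and a 4-fold change in a table otherwise without effect, with the same rule for the spread in each library. The model found 33% and 89% of them for proliferating against freshly isolated cells, with 8 false calls, and 47% and 89% for myotubes against proliferating cells, with 3 false calls. In the real data far more genes were called and some libraries stood apart, so these shares are not the sensitivity of the real fits.

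Genes were named in the text by a rule. They are the landmark genes of the stages that passed the filter, the 6 largest rises and 6 largest falls of each comparison (4 and 4 for myotubes against freshly isolated cells), up to 4 members of each list with the largest called change, and the 5 genes with the largest smaller of the 2 changes among those highest or lowest in proliferating cells. For the largest changes, genes had a symbol, an adjusted p below 0.05, no overlap between the libraries of the 2 stages and a mean of at least 100 in the higher stage, and numbered gene models, clone names, pseudogenes and small RNA genes were left out. Some genes that meet the rule are not reported here.

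The analysis ran in R 4.3.3 with limma 3.58.1 and in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.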

Results

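Gene expression was measured by RNA sequencing in mouse skeletal muscle stem cells, also called satellite cells, the resident cells from which adult muscle fibres are repaired. Cells of C57Bl6 mice aged 12 to 20 weeks were taken at 3 stages. They were freshly isolated from muscle, proliferating in a medium with 20% fetal calf serum and 2.5 ng/ml of the growth factor FGF-2 for at least 3 days, or fused into myotubes after 6 days in 2% horse serum. Each stage was sampled in 3 independent preparations from different animals, which gave 9 libraries. The deposited values were read counts per gene that had been scaled between libraries and rounded, and they are called normalized read counts here. They summed to 20.1 to 26.2 M in the freshly isolated, 17.8 to 18.2 M in the proliferating and 19.5 to 20.8 M in the myotube libraries. The spacing of the low values put the reads assigned to genes at an estimated 12.0 to 19.4 M, 20.4 to 24.3 M and 22.0 to 22.8 M per library of the same stages.

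The 9 libraries separated by stage. Pearson correlations of log2 values across genes lay between 0.926 and 0.991 for 2 libraries of one stage and between 0.63 and 0.916 for libraries of different stages. The first principal component, with 70.1% of the variance, set freshly isolated cells apart from both cultured stages, and the second, with 19.3%, separated proliferating cells from myotubes. The third, with 6.1%, set freshly isolated replicate 1 (score 104) apart from replicates 2 (-60.9) and 3 (-51.7). In that library the non-coding RNA gene Gm26917 took 22.2% of the total, against 10.6% and 11.2% in the other freshly isolated libraries. Values below are means ± SD of normalized read counts over 3 libraries per stage, and log2 changes are given ± SE on the log2(value + 1) scale. Folds are taken from the log2 changes and so differ from ratios of the means where libraries varied. When 1 library was left out, 102 of the 372 called log2 changes of named genes (375 in all) moved by more than 1.5-fold in either direction. Adjusted p-values come from limma with Benjamini-Hochberg adjustment over 17291 genes. Positions are on GRCm38. For each gene named as higher or lower the libraries of the stages compared did not overlap, with the exceptions of Myod1 in myotubes against freshly isolated cells and Pi16 in myotubes against proliferating cells.

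**Figure D1:**
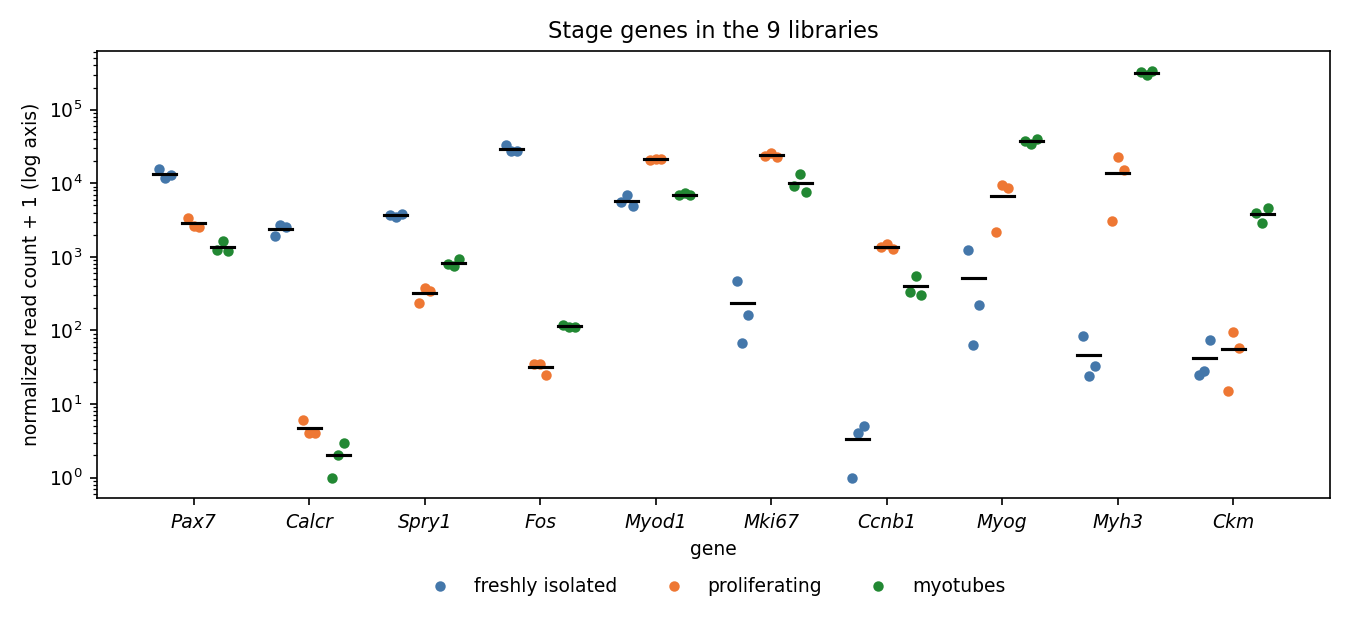
Normalized read count + 1 (log axis) of 10 stage genes in the 9 libraries, with 1 dot per library, coloured by stage, and a black bar at the mean of each stage. Calcr and Fos were high in the freshly isolated libraries alone, Mki67 and Ccnb1 were highest in the proliferating libraries, and Myog, Myh3 and Ckm were highest in the myotube libraries.

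The first comparison asked how satellite cells changed when they left the muscle and divided in culture. Proliferating cells had lost most of the transcripts that mark resting satellite cells. Pax7, the transcription factor that defines the lineage (chromosome 4, 139737062 to 139833528), fell from 13429 ± 2056 in freshly isolated to 2851 ± 418 in proliferating cells, a 4.7-fold decrease (log2 change -2.23 ± 0.16, adjusted p = 5.97e-07). Calcr, the calcitonin receptor that keeps satellite cells quiescent (chromosome 6, 3685680 to 3764714), fell from 2401 ± 411 to 3.67 ± 1.15 (log2 change -9.02 ± 0.43). Spry1, an inhibitor of growth factor signalling, fell 11.8-fold from 3698 ± 181 to 318 ± 75.2, and the surface antigen Cd34 fell from 3175 ± 821 to 88.7 ± 28.6. In the opposite direction Myod1, the transcription factor of committed myoblasts (chromosome 7, 46376474 to 46379099), rose 3.69-fold from 5782 ± 993 to 21146 ± 401 (log2 change 1.88 ± 0.12, adjusted p = 2.16e-07).

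Across all genes tested, 6507 were higher and 6172 lower in proliferating than in freshly isolated cells (limma, adjusted p below 0.05). Without freshly isolated replicate 1 and proliferating replicate 1, 2 libraries that stood apart from the others of their stage, the counts were 6791 and 6531. The lists of genes below were written before the data were examined, and the counts of members adjusted over the list alone were the same as those over all genes unless both are given. Of 27 quiescence genes, 23 were lower and 3 higher (adjusted over the list alone, 24 and 3), a list shift that camera called with adjusted p = 4.97e-07 (adjusted p = 0.152 with an estimated correlation). Chodl, a membrane lectin (chromosome 16, 78930948 to 78951733), fell from 11282 ± 1692 to 1.33 ± 1.53. Bmp6, a secreted growth factor, fell from 3928 ± 399 to 13 ± 2.65 (log2 change -8.15 ± 0.29), and Tek, the angiopoietin receptor, from 2017 ± 189 to 20.3 ± 6.66. Of 17 Notch pathway genes, 12 were lower and 5 higher, and the list as a whole was not called (adjusted p = 0.0964). The receptor Notch3 fell from 22304 ± 795 to 1674 ± 523 and its target Heyl from 6071 ± 396 to 252 ± 203, while Lfng, a glycosyltransferase that modifies Notch, rose from 14.7 ± 13.1 to 525 ± 92.4.

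All 27 immediate early and dissociation stress genes were lower in proliferating cells (camera adjusted p = 1.2e-15, and adjusted p = 0.0465 with an estimated correlation). Fosb, a subunit of the transcription factor AP-1 (chromosome 7, 19302696 to 19310051), fell from 75520 ± 14876 to 12 ± 5.2 (log2 change -12.56 ± 0.26, adjusted p = 2.82e-10), and its relative Fos from 29135 ± 3109 to 30.7 ± 5.77. The heat shock genes Hspa1a and Hspa1b fell from 72301 ± 1502 to 24.3 ± 1.53 and from 104134 ± 11234 to 98.3 ± 13.3. Their split is uncertain because the genes are near-identical copies. Interferon response genes were lower in 13 and higher in 2 of 15 members (camera adjusted p = 0.00189, and adjusted p = 0.138 with an estimated correlation). Among them Ifih1, a sensor of double-stranded RNA, fell from 525 ± 67.9 to 18 ± 6, and Oasl2 from 198 ± 95.8 to 5.67 ± 4.73.

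Cell division genes rose together. Each of the 25 mitotic cell cycle genes was higher in proliferating cells (camera adjusted p = 1.01e-10, and adjusted p = 0.138 with an estimated correlation). So was each of the 32 DNA replication genes (camera adjusted p = 1.01e-10, and adjusted p = 0.29 with an estimated correlation). Mki67, the usual proliferation marker (chromosome 7, 135689784 to 135716361), rose from 233 ± 211 to 23936 ± 1483, with log2 changes of 7.83 without freshly isolated replicate 1 and 6.42 without replicate 2. Cdk1, the kinase that starts mitosis (chromosome 10, 69335146 to 69352938), rose from 4.67 ± 7.23 to 3092 ± 230 (log2 change 9.99 ± 0.74, and 9.19 without freshly isolated replicate 1 or 11.09 without replicate 3), and Plk1, another mitotic kinase, from 17.7 ± 26.3 to 2095 ± 143. Rrm2, which makes DNA precursors, rose 101-fold from 137 ± 30.8 to 13729 ± 826, and the replicative helicase subunit Mcm2 from 217 ± 171 to 5189 ± 326. Freshly isolated replicate 1 lay above both other freshly isolated libraries in 14 of the 25 mitotic and 19 of the 32 replication genes, with Mki67 at 471 against 66 and 163. Other members went the other way. Without this library the log2 changes of Ccnb1 (8.99) and Aurka (7.82) fell to 8.27 and 6.19. The share of all genes highest in this library was not counted, so no rise of these lists beyond that share is claimed. Of 16 cell cycle inhibitor genes 6 were higher and 8 lower (not called, adjusted p = 0.576). Btg2 and Btg1, inhibitors of division, fell from 7926 ± 412 to 142 ± 37.5 and from 15545 ± 1813 to 762 ± 157, while Cdkn1a, the inhibitor p21, had a log2 change of 0.30 (adjusted p = 0.317) between 2535 ± 24.5 and 3333 ± 1290. Without proliferating replicate 1 the log2 change of Cdkn1a was 0.68 (limma, adjusted p = 0.00134).

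Part of the muscle programme was already higher in the proliferating libraries. Which cells of these cultures held the transcripts was not tested. Myog, the transcription factor of differentiating myoblasts (chromosome 1, 134289989 to 134292548), rose from 512 ± 650 to 6819 ± 4038 (log2 change 4.45 ± 0.91, adjusted p = 0.00128). Without freshly isolated replicate 1 or 2 the log2 change of Myog was 5.59 or 3.43, and without proliferating replicate 1 it was 5.14. Myh3, embryonic myosin heavy chain, rose from 46 ± 32.4 to 13826 ± 10082, and Acta1, skeletal muscle actin, from 126 ± 3.51 to 11119 ± 7747. Of 34 sarcomere genes 22 were higher and 6 lower (camera adjusted p = 0.00181, and adjusted p = 0.7 with an estimated correlation). These genes varied between libraries of one stage. Proliferating replicate 1 lay below both others in 33 of the 34, with Myh3 at 3055 against 23038 and 15385, and Myog at 2179 against 9530 and 8749. Freshly isolated replicate 1 lay above both others in 16 of the 34, a count without a share over all genes beside it. Its Myog value was 1257 against 62 and 218. Ckm, the muscle creatine kinase of mature fibres, did not differ past the threshold (41.3 ± 27.5 and 55 ± 40, adjusted p = 0.758). Of 22 excitation-contraction coupling genes 12 were higher and 7 lower (not called, adjusted p = 0.32), with Cacna1s, the voltage sensor of muscle, rising from 5 ± 7.81 to 277 ± 196 and the calcium release channel Ryr3 falling from 667 ± 184 to 26 ± 8.19. Among 12 neuromuscular junction genes 7 were higher and 5 lower (not called, adjusted p = 0.39). The acetylcholine receptor subunit genes Chrna1 and Chrng rose from 589 ± 27 to 19669 ± 1657 and from 10.7 ± 7.57 to 1987 ± 707. Of 21 myoblast fusion genes 13 were higher and 4 lower (adjusted over the list alone, 13 and 6), and the list was not called (adjusted p = 0.125), though it was without the 2 libraries that stood apart (camera adjusted p = 0.0283). Tmem8c, which encodes the fusion protein myomaker, rose from 63.3 ± 83.6 to 923 ± 535. Myf6 rose from 8.67 ± 8.08 to 31.7 ± 5.86 (log2 change 2.50 ± 0.84, limma adjusted p = 0.0211). This call was lost without proliferating replicate 2 (adjusted p = 0.0583) or 3 (0.0559), and without freshly isolated replicate 1 or 2 the log2 change was 1.24 or 3.28.

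Among metabolic genes, 27 of 30 members of the oxidative phosphorylation and TCA cycle list were higher and 1, Cox7a1, was lower (camera adjusted p = 4.25e-08, and adjusted p = 0.54 with an estimated correlation). Sdhd, a succinate dehydrogenase subunit, rose 8.23-fold from 280 ± 28 to 2305 ± 136, and Idh3a, an isocitrate dehydrogenase subunit, from 797 ± 160 to 5936 ± 349. The 13 protein genes of mitochondrial DNA were listed at 0 in all 9 libraries and could not be compared. Of 26 glycolysis and phosphocreatine genes 15 were higher and 7 lower (not called, adjusted p = 0.106), with Eno3, the muscle enolase, rising from 248 ± 81.1 to 9914 ± 742. Of 21 fatty acid oxidation genes 12 were higher and 4 lower (not called, adjusted p = 0.35). Ribosome biogenesis genes were higher in 14 and lower in 2 of 26 members (camera adjusted p = 0.0434, and adjusted p = 0.7 with an estimated correlation), among them Rrn3, a factor of RNA polymerase I, which rose 3.25-fold. That list was no longer called without freshly isolated replicate 2 (adjusted p = 0.0859), freshly isolated replicate 3 (0.108) or proliferating replicate 1 (0.0776).

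The lists of extracellular matrix, chromatin, imprinted, growth factor signalling and myogenic transcription factor genes moved in both directions and were not called. The extracellular matrix list had 10 higher and 10 lower of 24 (adjusted p = 0.882). Collagen VI gene Col6a1 fell from 9596 ± 3240 to 147 ± 92, whereas Tnc, the adhesion-modulating tenascin C, rose from 145 ± 85.6 to 5076 ± 1986. Chromatin and DNA methylation enzymes had 16 higher and 12 lower of 32 (adjusted over the list alone, 17 and 12; adjusted p = 0.785). Uhrf1, needed for maintenance of DNA methylation, rose from 122 ± 96.6 to 3635 ± 298, and the histone demethylase gene Kdm6b fell 23.5-fold from 30264 ± 1466 to 1289 ± 116. Imprinted genes had 5 higher and 8 lower of 15 (adjusted p = 0.39). The non-coding RNA genes Meg3 (chromosome 12, 109541001 to 109571726) and Rian, neighbours in one imprinted domain, fell from 27115 ± 2906 to 76 ± 16.6 and from 15660 ± 1989 to 98 ± 19.1, and H19 (chromosome 7, 142575529 to 142578143) rose from 500 ± 60.2 to 92730 ± 11580. In FGF and HGF signalling 6 were higher and 9 lower of 16 (adjusted p = 0.265), with the receptor Fgfr1 falling 9.02-fold from 38327 ± 1181 to 4254 ± 323. Myogenic transcription factors had 10 higher and 9 lower of 21 (adjusted p = 0.869). The median, mean and test of a list differed in sign for this list (median -0.18, mean 0.14, test lower) and for the extracellular matrix (median 0.04, mean -0.08, test lower).

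Most called markers of other cell types were lower in culture, and no marker list was called. Endothelial markers were lower in 4 of 6 tested, with Pecam1 at 114 ± 49.5 in freshly isolated and 34.3 ± 7.64 in proliferating cells. Leukocyte markers were lower in 3 of 5, with Cd68 falling from 600 ± 44.1 to 61 ± 9.54. Fibroblast markers were lower in 4 and higher in 1 of 6. Of these, Dpt, which encodes the matrix protein dermatopontin, had 2449, 3554 and 3249 in the freshly isolated libraries and was listed at 0 in each proliferating library. Cxcl14, a chemokine gene, had 113, 63 and 131 and was likewise listed at 0. Pericyte or smooth muscle markers were higher in 2 and lower in 3 of 7, Schwann cell markers lower in 3 of 4, adipocyte markers lower in 2 of 2, and tenocyte markers higher in 1 and lower in 1 of 4. The one erythroid marker tested, Alas2, was higher in proliferating cells, and adult myofibre markers were higher in 3 and lower in 4 of 10. The fibroblast marker Pi16 lost its call without proliferating replicate 1 (limma adjusted p = 0.0785) and without freshly isolated replicate 2 (0.0501) or 3 (0.0651).

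The largest rises outside these lists were those of Hmga2, a chromatin protein of growing cells (chromosome 10, 120361275 to 120476469), from 0.67 ± 1.15 to 3409 ± 1423, and of St8sia2, which adds polysialic acid to NCAM, from 2 ± 2 to 5288 ± 795. Spp1, which encodes osteopontin, rose from 9.67 ± 14.2 to 8736 ± 2182, Asns, asparagine synthetase, from 1.67 ± 2.89 to 2664 ± 179, Dusp27 from 1.67 ± 2.89 to 2853 ± 793 and the semaphorin gene Sema3e from 0.33 ± 0.58 to 1694 ± 150. Besides Fosb, Chodl and Dpt, the largest falls were those of Prelp, a matrix proteoglycan gene, from 6928 ± 570 to 0.33 ± 0.58, Medag, from 5392 ± 516 to 0.67 ± 0.58, and Itih5, a hyaluronan-binding protein gene, from 13475 ± 1473 to 3.33 ± 2.31. Where the lower stage lay at 3 or less, the fitted log2 change depends on the pseudocount and no fold is given. Other scalings moved the median of all genes by up to 0.142 on the log2 scale in this comparison, so smaller changes are relative to that.

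**Figure D2:**
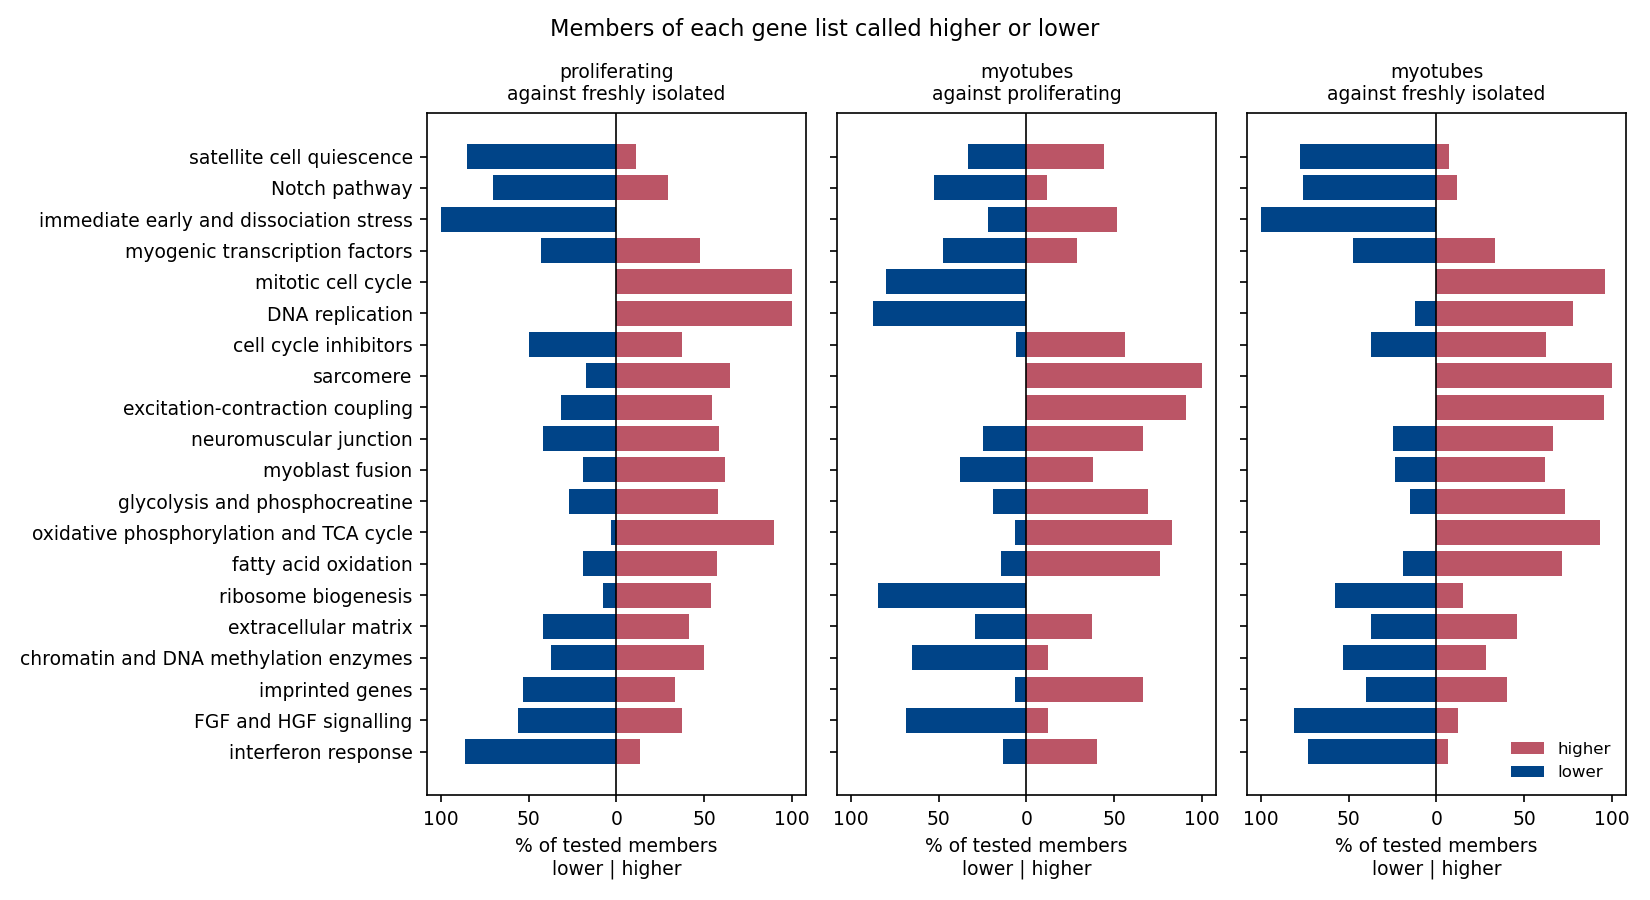
Percent of the tested members of each of 20 gene lists that were called higher (right of 0) or lower (left of 0), in 3 panels for the 3 comparisons, from limma with adjusted p below 0.05. All 32 DNA replication genes were higher in proliferating than in freshly isolated cells, and all 34 sarcomere genes were higher in myotubes than in either other stage.

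The second comparison asked what changed when proliferating cells were made to differentiate. Myotubes had far more of the transcripts of the contractile apparatus and less of those for DNA replication. Myh3 rose 30.9-fold from 13826 ± 10082 in proliferating cells to 318334 ± 20091 in myotubes (log2 change 4.95 ± 0.67, adjusted p = 0.000134), and Acta1 rose 19.3-fold (log2 change 4.27 ± 0.53) to 165831 ± 20747. Ckm (chromosome 7, 19404776 to 19422841) rose 85.5-fold from 55 ± 40 to 3787 ± 848 (log2 change 6.42 ± 0.62). Cdkn1c, the cell cycle inhibitor p57 (chromosome 7, 143458339 to 143461050), rose from 71.3 ± 41.7 to 14116 ± 1108 (log2 change 7.84 ± 0.86). Without proliferating replicate 1, which was low in muscle genes, the log2 changes were 4.08 for Myh3, 3.46 for Acta1, 5.65 for Ckm and 7.22 for Cdkn1c. Myod1 fell 3-fold from 21146 ± 401 to 7043 ± 241, and Pax7 fell 2.1-fold from 2851 ± 418 to 1364 ± 246.

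In this comparison 4951 genes were higher and 4402 lower in myotubes (limma, adjusted p below 0.05). The counts were 5727 and 4986 without freshly isolated replicate 1 and proliferating replicate 1. Without freshly isolated replicate 1 alone, which is not in this comparison, they were 5961 and 5343, because the fit shares 1 spread among all stages. Without proliferating replicate 1 alone they fell to 4363 and 3742. A fit of only the 2 groups compared gave 6098 and 5416. Genes on the X and Y chromosomes were also left out, because the sex-linked genes differed by stage. The counts were then 4760 and 4260 with all 9 libraries. Xist, the RNA that silences 1 X chromosome in female cells (chromosome X, 103460366 to 103483254), was at 10966 or more in each freshly isolated and proliferating library and at 3 or less in each myotube library. No stage had libraries of both kinds, so the stage could not be separated from this difference. The Y-linked genes Ddx3y, Eif2s3y and Kdm5d rose from 0.67 ± 0.58, 1.33 ± 1.53 and 0.67 ± 1.15 to 3435 ± 244, 2589 ± 199 and 1363 ± 62.3. These 3 and Xist were among the 6 largest rises and the 6 largest falls of the comparison. On the X chromosome 185 of 576 tested genes were higher and 142 lower, and of the 6 tested Y genes 5 were higher and 1 lower.

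**Figure D3:**
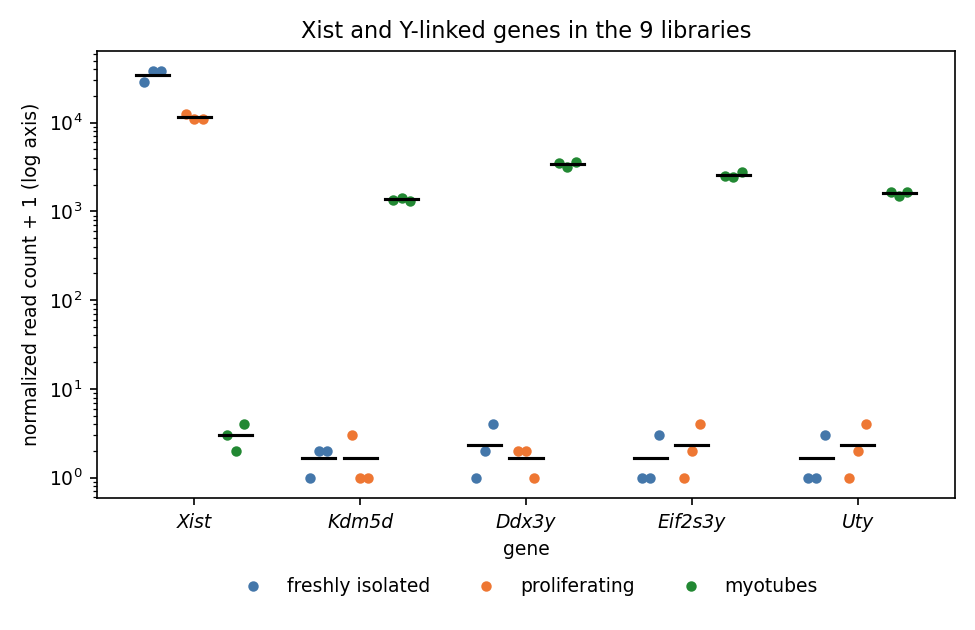
Normalized read count + 1 (log axis) of Xist and 4 Y-linked genes in the 9 libraries, with 1 dot per library, coloured by stage, and a black bar at the mean of each stage. Xist was at 10966 or more in the freshly isolated and proliferating libraries and at 3 or less in the myotube libraries, and the Y-linked genes were detected above a value of 3 in the myotube libraries alone.

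All 34 sarcomere genes were higher in myotubes (camera adjusted p = 1.13e-13, and adjusted p = 0.229 with an estimated correlation). Myh8, perinatal myosin heavy chain (chromosome 11, 67277124 to 67308634), rose from 118 ± 105 to 52769 ± 6567, Myh7, the slow isoform, from 54.7 ± 38.9 to 8984 ± 612, and Tcap, a titin-binding protein of the Z disc, from 6.67 ± 3.06 to 1735 ± 485. Proliferating replicate 1 lay below both others of its stage in 33 of these 34 genes and in 18 of the 22 excitation-contraction coupling genes. Of those 22 genes 20 were higher (camera adjusted p = 7.18e-09, and adjusted p = 0.217 with an estimated correlation). Casq1 and Casq2, the calcium-binding calsequestrins of the sarcoplasmic reticulum, rose from 20 ± 14.8 to 22396 ± 2178 and from 280 ± 214 to 32539 ± 3172, and Trdn, their membrane anchor triadin, from 31.7 ± 23.8 to 9654 ± 1388. All 10 adult myofibre markers were higher (camera adjusted p = 9.28e-06, and adjusted p = 0.229 with an estimated correlation). Mb, the oxygen store myoglobin, rose from 145 ± 75.7 to 19269 ± 4021, and Myh1, a fast adult myosin, from 780 ± 599 to 91362 ± 11060. Of these 10 markers 7 are also on the sarcomere list, so the lists are not separate evidence.

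Of 21 myogenic transcription factors 6 were higher and 10 lower (not called, adjusted p = 0.255). Mef2c, a transcription factor of muscle genes (chromosome 13, 83504034 to 83667080), rose from 175 ± 133 to 29686 ± 3248, and Myf6 rose 38.2-fold to 1240 ± 166. Myog was at 37111 ± 3034 in myotubes (log2 change 2.71 ± 0.91, limma adjusted p = 0.0285), a call that was lost without proliferating replicate 1 (log2 change 2.02, adjusted p = 0.113) and without myotube replicate 1 (0.0688), 2 (0.0639) or 3 (0.0743). It was also lost under quantile normalization (limma adjusted p = 0.0546). The fit shares 1 spread among all stages. On the log2 scale Myog varied most among the freshly isolated libraries, which are not in this comparison. In the fit of only the 2 groups compared the call of Myog was kept. Msc, a repressor of the same gene family, rose from 12 ± 7.21 to 36 ± 6.56 (log2 change 1.70 ± 0.44, and 1.12 without proliferating replicate 3). Myf5, expressed in satellite cells and myoblasts, fell from 1462 ± 204 to 1084 ± 75.8 (log2 change -0.42 ± 0.13, limma adjusted p = 0.0183), and its call was lost without proliferating replicate 1 (0.073) or 2 (0.0578) and without myotube replicate 1 (0.0605) or 3 (0.0642). Neuromuscular junction genes were higher in 8 and lower in 3 of 12 (not called, adjusted p = 0.134), with the fetal receptor subunit gene Chrng rising 5.22-fold to 9910 ± 1191. Myoblast fusion genes were higher in 8 and lower in 8 of 21 (not called, adjusted p = 0.603). Tmem8c rose to 12093 ± 1312 (log2 change 3.93 ± 1.00, and 3.33 without proliferating replicate 1), and Gm7325, which encodes the fusion peptide myomerger, from 152 ± 104 to 970 ± 90. Dysf, the membrane repair gene dysferlin, rose from 312 ± 155 to 1713 ± 246 (log2 change 2.60 ± 0.75), a call lost without proliferating replicate 1 (adjusted p = 0.0598).

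Cell division genes fell, most of them to a level above that of freshly isolated cells. Of 32 DNA replication genes 28 were lower and none higher (adjusted over the list alone, 30 and 0; camera adjusted p = 1.98e-11, and adjusted p = 0.217 with an estimated correlation). Cdt1, which licenses replication origins, fell 6.91-fold from 1572 ± 155 to 229 ± 47.1, and the helicase subunit Mcm3 6.31-fold from 5351 ± 321 to 863 ± 207. Of 25 mitotic cell cycle genes 20 were lower and 0 higher (adjusted over the list alone, 23 and 0; camera adjusted p = 1.54e-07, and adjusted p = 0.217 with an estimated correlation). Mybl2, a transcription factor of dividing cells, fell 11.5-fold from 1399 ± 303 to 122 ± 30.5, and Ccnb1, the mitotic cyclin B1 (chromosome 13, 100778650 to 100786570), fell from 1378 ± 103 to 395 ± 137. Mki67 was at 23936 ± 1483 in proliferating cells and 10000 ± 2901 in myotubes (log2 change -1.30 ± 0.54, limma adjusted p = 0.0671). It passed the threshold without freshly isolated replicate 1 (adjusted p = 0.00224) or 2 (0.0111), because the fit shares 1 spread among all stages. Cell cycle inhibitors were higher in 9 and lower in 1 of 16 (camera adjusted p = 0.00205, and adjusted p = 0.217 with an estimated correlation), with Cdkn1a rising 5.61-fold from 3333 ± 1290 to 17745 ± 2853 and Ccng1, a p53 target, 7.26-fold to 20455 ± 3333.

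Energy metabolism genes rose as groups. In the oxidative phosphorylation and TCA cycle list 25 of 30 were higher and 2 lower (camera adjusted p = 4.4e-08, and adjusted p = 0.316 with an estimated correlation). The muscle isoforms of cytochrome c oxidase, Cox6a2 and Cox8b, rose from 4.67 ± 4.73 to 1968 ± 642 and from 10 ± 5 to 2235 ± 758. Fatty acid oxidation genes were higher in 16 and lower in 3 of 21 (camera adjusted p = 6.76e-05, and adjusted p = 0.217 with an estimated correlation), with Fabp3, a fatty acid carrier, rising from 12.7 ± 10.5 to 2520 ± 324 and Ppargc1a, a coactivator of mitochondrial genes, 4.46-fold from 143 ± 18.4 to 638 ± 52.1. Glycolysis and phosphocreatine genes were higher in 18 and lower in 5 of 26 (camera adjusted p = 0.00137, and adjusted p = 0.347 with an estimated correlation). Pygm, muscle glycogen phosphorylase, rose 32.5-fold from 169 ± 76.7 to 5132 ± 1143. Ribosome biogenesis genes were lower in 22 and higher in 0 of 26 (camera adjusted p = 5.5e-08, and adjusted p = 0.229 with an estimated correlation). Ncl, nucleolin, fell 3.05-fold from 53833 ± 9601 to 17546 ± 1758, and Npm1, nucleophosmin, 3.08-fold from 25447 ± 2657 to 8272 ± 883.

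Imprinted genes were higher in 10 and lower in 1 of 15 (adjusted over the list alone, 11 and 1; camera adjusted p = 0.00029, and adjusted p = 0.217 with an estimated correlation). Meg3 rose from 76 ± 16.6 to 863 ± 180 and Rian from 98 ± 19.1 to 2982 ± 651, both below their freshly isolated levels. FGF and HGF signalling genes were lower in 11 and higher in 2 of 16 (camera adjusted p = 0.00029, and adjusted p = 0.217 with an estimated correlation), with the HGF receptor Met falling 6.3-fold from 11431 ± 902 to 1823 ± 283. Spry1, a feedback inhibitor on this list, rose from 318 ± 75.2 to 830 ± 103. Chromatin and DNA methylation enzymes were lower in 21 and higher in 4 of 32 (camera adjusted p = 0.00107, and adjusted p = 0.217 with an estimated correlation). The maintenance methyltransferase gene Dnmt1 fell 4.99-fold from 9494 ± 556 to 1928 ± 402, and Hdac9, a histone deacetylase gene, rose from 12.3 ± 7.64 to 214 ± 8.66. The collagen genes Col1a1 and Col1a2 rose from 20.3 ± 5.86 to 708 ± 110 and from 577 ± 231 to 5728 ± 586, and thrombospondin 1, Thbs1, fell 10.5-fold to 2645 ± 287.

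The remaining lists were not called in this comparison. Quiescence genes were higher in 12 and lower in 9 of 27 (adjusted over the list alone, 12 and 10; adjusted p = 0.978), and Calcr, at 3.67 ± 1.15 and 1 ± 1, was called (limma adjusted p = 0.0244) at values where the change depends on the pseudocount. Its call was lost without proliferating replicate 1 (0.0808) or myotube replicate 1 (0.0815). Notch pathway genes were higher in 2 and lower in 9 of 17 (adjusted p = 0.0686, and 0.0126 without the 2 libraries that stood apart). Immediate early genes were higher in 14 and lower in 6 of 27 (adjusted p = 0.603), extracellular matrix genes higher in 9 and lower in 7 of 24 (adjusted p = 0.645), and interferon response genes higher in 6 and lower in 2 of 15 (adjusted over the list alone, 8 and 2; adjusted p = 0.358). Of the interferon genes, Ifit1 and Bst2 lost their calls without proliferating replicate 3 (limma adjusted p = 0.0581 and 0.0573), Ifit1 also without proliferating replicate 1 (0.0716) or myotube replicate 2 (0.0803), and Bst2 without myotube replicate 3 (0.0523). Among the markers, endothelial ones were lower in 3 of 6, leukocyte ones higher in 1 and lower in 2 of 5, fibroblast ones lower in 2 of 6 (of which Pi16 lost its call without proliferating replicate 2, 0.0973, or 3, 0.116, or myotube replicate 1, 0.125, or 3, 0.0674), and pericyte or smooth muscle ones higher in 4 and lower in 1 of 7. Tenocyte markers were higher in 2 of 4 (adjusted over the list alone, 3), the erythroid marker Alas2 was lower, and of the 4 Schwann cell and 2 adipocyte markers 0 were called (limma). The median, mean and test differed in sign for quiescence (median 0.17, mean 0.37, test lower), myogenic transcription factors (-0.25, 0.44, lower), myoblast fusion (-0.12, 0.57, lower) and leukocyte markers (-1.1, 0.13, lower).

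Outside the lists and the sex-linked genes, the largest rises were those of Ppp1r3a, a glycogen-targeting phosphatase subunit of muscle, from 0.33 ± 0.58 to 2393 ± 454, and Myot, the Z disc protein myotilin, from 1 ± 1.73 to 2193 ± 491. The largest falls were those of Fibcd1, an acetyl-group-binding membrane receptor gene, from 418 ± 132 to 3.67 ± 2.08, the glutamate receptor gene Grik3, from 915 ± 404 to 10.7 ± 6.03, P-selectin, Selp, from 225 ± 80.7 to 2 ± 1, the p53-inducible gene Trp53i11, from 4520 ± 432 to 72.7 ± 23.5, and the adhesion molecule gene Igsf11, from 437 ± 58.2 to 6.33 ± 0.58. Quantile normalization moved the median of all genes by -0.141 on the log2 scale in this comparison, and smaller changes are relative to that. It turned the balance of calls to 4329 higher and 5174 lower, and TMM scaling gave 4628 higher and 4669 lower, so no excess of rises over falls is claimed.

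The third comparison set the end of the culture against its start. Myotubes carried high levels of muscle protein transcripts that were scarce in freshly isolated cells, and they kept little of the satellite cell signature. Myh3 was at 46 ± 32.4 in freshly isolated cells and 318334 ± 20091 in myotubes (log2 change 12.94 ± 0.67, adjusted p = 4.98e-08), and Myog rose from 512 ± 650 to 37111 ± 3034 (log2 change 7.16 ± 0.91, and 8.30 without freshly isolated replicate 1 or 6.14 without replicate 2). Mylpf, a fast myosin light chain, rose from 34.3 ± 28.8 to 124137 ± 29680. Pax7 fell 9.87-fold to 1364 ± 246, Cd34 from 3175 ± 821 to 8.67 ± 6.43 and Calcr from 2401 ± 411 to 1 ± 1. The counts were 6959 genes higher and 6457 lower (limma, adjusted p below 0.05), 7326 and 6947 without the 2 libraries that stood apart, and 6706 and 6285 without the X and Y genes. Myod1 was at 5782 ± 993 and 7043 ± 241 (log2 change 0.30 ± 0.12, limma adjusted p = 0.0357), and its call was lost without freshly isolated replicate 1 (0.0573) or 3 (0.147), proliferating replicate 3 (0.0518), or myotube replicate 1 (0.0731), 2 (0.0963) or 3 (0.0628).

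All 34 sarcomere genes were higher (camera adjusted p = 1.09e-10, and adjusted p = 0.301 with an estimated correlation), as were 21 of 22 excitation-contraction coupling genes (camera adjusted p = 2.56e-06, and adjusted p = 0.301 with an estimated correlation) and all 10 adult myofibre markers (camera adjusted p = 0.00125, and adjusted p = 0.309 with an estimated correlation). Cacna1s rose from 5 ± 7.81 to 5728 ± 434 and Tnnt3, fast troponin T, from 426 ± 22.6 to 64137 ± 12930. Freshly isolated replicate 1 lay above both others in 16 of the 34 sarcomere genes, and the share over all genes was not counted. Oxidative phosphorylation and TCA cycle genes were higher in 28 and lower in 0 of 30 (camera adjusted p = 1.09e-10, and adjusted p = 0.301 with an estimated correlation). Glycolysis and phosphocreatine genes were higher in 19 and lower in 4 of 26 (camera adjusted p = 0.0014, and adjusted p = 0.309 with an estimated correlation), and fatty acid oxidation genes higher in 15 and lower in 4 of 21 (camera adjusted p = 0.00558, and adjusted p = 0.301 with an estimated correlation). Ndufa9, a complex I subunit, rose 18.3-fold from 222 ± 25.1 to 4097 ± 621, and Pgam2, the muscle phosphoglycerate mutase, from 30.7 ± 11.9 to 6127 ± 890.

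Most cell division genes were still higher in the myotube libraries than in freshly isolated cells, with exceptions among the DNA replication genes. Whether these transcripts came from the myotubes or from any unfused cells in the cultures was not tested. Of 25 mitotic genes 24 were higher and 0 lower (camera adjusted p = 4.01e-07, and adjusted p = 0.188 with an estimated correlation), and of 32 DNA replication genes 25 were higher and 4 lower (camera adjusted p = 0.00145, and adjusted p = 0.383 with an estimated correlation). Top2a, the topoisomerase of dividing cells, was at 113 ± 83.6 in freshly isolated cells and 6059 ± 1425 in myotubes, and Mki67 at 233 ± 211 and 10000 ± 2901. Freshly isolated replicate 1 lay above both others in 14 of the 25 mitotic and 19 of the 32 replication genes, without a share over all genes for comparison. Cell cycle inhibitors were higher in 10 and lower in 6 of 16 (not called, adjusted p = 0.404). Cdkn2a and Cdkn2b, inhibitors of the G1 kinases, rose from 17.7 ± 22.8 to 313 ± 16 and from 17.7 ± 3.79 to 276 ± 79.3.

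Quiescence genes were lower in 21 and higher in 2 of 27 (camera adjusted p = 3.19e-06, and adjusted p = 0.188 with an estimated correlation). Notch pathway genes were lower in 13 and higher in 2 of 17 (camera adjusted p = 0.00397, and adjusted p = 0.301 with an estimated correlation), with the ligand gene Jag1 falling 11.3-fold from 2037 ± 52 to 180 ± 30.1. Lfng was at 14.7 ± 13.1 and 173 ± 81.1 (log2 change 4.34 ± 1.00), and its log2 change was 2.84, 5.19 and 5.00 without freshly isolated replicate 1, 2 and 3. All 27 immediate early genes were lower (camera adjusted p = 2.15e-14, and adjusted p = 0.0576 with an estimated correlation), with Fos at 29135 ± 3109 and 113 ± 3.06. FGF and HGF signalling genes were lower in 13 and higher in 2 of 16 (camera adjusted p = 0.000911, and adjusted p = 0.188 with an estimated correlation), and the syndecan gene Sdc4 fell 97.5-fold from 70876 ± 15064 to 717 ± 58.7. Interferon response genes were lower in 11 and higher in 1 of 15 (camera adjusted p = 0.00752, and adjusted p = 0.188 with an estimated correlation), among them the transcription factor genes Irf9 and Irf7, which fell from 1915 ± 113 to 81 ± 11.3 and from 235 ± 19.1 to 20.7 ± 3.79. Fibroblast markers were lower in 5 and higher in 1 of 6 (camera adjusted p = 0.042, and adjusted p = 0.301 with an estimated correlation), a call lost without freshly isolated replicate 3 (0.0534). Dcn, the proteoglycan decorin, fell from 750 ± 310 to 4.67 ± 3.21.

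The other lists were not called. Imprinted genes were higher in 6 and lower in 6 of 15 (adjusted p = 0.907), with H19 reaching 323502 ± 26252 and Igf2, the growth factor, 77272 ± 2107 from 3031 ± 753. Ribosome biogenesis genes were higher in 4 and lower in 15 of 26 (adjusted p = 0.0829), chromatin enzymes higher in 9 and lower in 17 of 32 (adjusted over the list alone, 9 and 18; adjusted p = 0.0724), and extracellular matrix genes higher in 11 and lower in 9 of 24 (adjusted p = 0.907). Smyd1, a muscle histone methyltransferase gene, rose from 21 ± 15.1 to 9696 ± 200, and periostin, Postn, from 8 ± 4.58 to 2711 ± 136. Neuromuscular junction genes were higher in 8 and lower in 3 of 12 (adjusted over the list alone, 9 and 3; adjusted p = 0.0786), and myoblast fusion genes higher in 13 and lower in 5 of 21 (adjusted p = 0.107). Without the 2 libraries that stood apart both lists were called (camera adjusted p = 0.0396 and 0.0414). Myogenic transcription factors were higher in 7 and lower in 10 of 21 (adjusted p = 0.327; median -0.45, mean 0.58, test lower). Endothelial markers were lower in 5 of 6 and leukocyte markers lower in 4 of 5, with Itgam, an integrin of myeloid cells, rising from 3.33 ± 2.31 to 222 ± 8.08. Pericyte or smooth muscle markers were higher in 2 and lower in 2 of 7 (median -0.02, mean 0.04, test lower), with smooth muscle actin, Acta2, rising from 2247 ± 811 to 60967 ± 636. Schwann cell markers were lower in 4 of 4, tenocyte markers higher in 1 and lower in 2 of 4, adipocyte markers lower in 2 of 2, and Alas2 was lower. Among these markers, Sox10 lost its call without freshly isolated replicate 2 (limma adjusted p = 0.0508) or myotube replicate 1 (0.0799), and Alas2 without freshly isolated replicate 2 (0.0652) or myotube replicate 2 (0.0653) or 3 (0.082).

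Apart from Xist and Fosb, the largest falls were those of Tnxb, a matrix tenascin gene, from 19825 ± 4242 to 7.33 ± 4.93, and of Rbpjl, a relative of the Notch effector Rbpj. Rbpjl had 2033, 2227 and 1936 in the freshly isolated libraries, 1, 1 and 2 in the proliferating libraries and was listed at 0 in the 3 myotube libraries. The largest rises were those of Myh8, Myh3, Mylpf and Casq2.

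Genes were also sorted by whether their level in proliferating cells lay above or below both other stages. There were 2109 genes higher in proliferating cells than in both, where 1657 would be shared by independent lists of the same sizes, and 1885 lower than in both, where 1767 would be. Both comparisons use the same proliferating libraries. In 20 simulated tables with no effect 0 genes were found in either direction (limma). Without effects almost no gene can be called, so this does not show how far the shared libraries raised the counts above those of independent lists. The changes on entering and on leaving proliferation had a correlation across genes of -0.145, against -0.445 in simulated tables with no effect, and a covariance of -0.5 against -0.054. The simulated correlation was bound to be negative, because the 2 changes share the proliferating libraries with opposite sign. The gap between the 2 correlations therefore does not measure how far the changes opposed each other. Among the genes highest in proliferating cells, Trp53i11 (chromosome 2, 93187548 to 93201759) had 34.3 ± 19.9 in freshly isolated cells, 4520 ± 432 in proliferating cells and 72.7 ± 23.5 in myotubes. Adgrg3, an adhesion receptor gene, had 11.3 ± 12.7, 527 ± 93.8 and 9 ± 5.2 in the same order, Selp 4 ± 4.58, 225 ± 80.7 and 2 ± 1, and Igsf11 0.67 ± 1.15, 437 ± 58.2 and 6.33 ± 0.58. Among those lowest in proliferating cells, Dmd, the dystrophin gene (chromosome X, 82948870 to 85206141), had 14679 ± 2250, 137 ± 13.6 and 16707 ± 1354. Col15a1, a basement membrane collagen gene, had 5035 ± 1396, 2 ± 1.73 and 304 ± 159, and Fxyd1, a regulator of the sodium pump, 279 ± 6.93, 0.67 ± 0.58 and 376 ± 112. Adamts15, a matrix protease gene, had 258 ± 28.1, 2.67 ± 3.79 and 242 ± 74, and Igtp, an interferon-induced GTPase gene, 315 ± 63.6, 2.33 ± 1.15 and 140 ± 22.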

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

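The planned tests on counts were not run, because the values are scaled and rounded and are not counts. TMM and median-of-ratios factors were computed by own code. Fits without X and Y genes, with library quality weights and without the 2 libraries that stood apart were added after the data were seen.

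Over all settings other than the fold threshold, genes higher and lower numbered 5834 to 7015 and 4619 to 6852 in proliferating against freshly isolated cells, 4164 to 6452 and 3695 to 5772 in myotubes against proliferating cells, and 6085 to 7757 and 4799 to 7197 in myotubes against freshly isolated cells. Over these settings without the fit of only 2 groups, genes highest in proliferating cells numbered 1757 to 2736 and lowest 1615 to 2481. With a fold threshold of log2 1, proliferating against freshly isolated cells gave 4707 genes higher and 4843 lower, myotubes against proliferating cells 3152 genes higher and 2514 lower, and myotubes against freshly isolated cells 5479 and 5217, with 956 for the genes highest in proliferating cells and 1080 for the genes lowest in proliferating cells. With the replicate number as a replicate block the counts were 6446 and 6117, 4843 and 4245, and 6916 and 6395 in the same order. Deviations of equally numbered libraries correlated at -0.034 to 0.027, which gave no sign that the numbers pair the samples. With 3 libraries per stage this cannot exclude a pairing. Leaving out any 1 library gave 5980 to 6810 and 5769 to 6608, 4164 to 5961 and 3695 to 5343, and 6517 to 7262 and 6053 to 6870.

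In the gene list tests, 8, 13 and 14 lists were called in the 3 comparisons by camera, and 1, 0 and 0 with an estimated correlation. Camera sets a list against the other genes. The directional test of fry asks whether members shifted in the same direction on balance, without setting them against other genes. With this other question 23, 19 and 25 lists were called. A list that moved in both directions can be missed by it.

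Of 375 log2 changes of named genes 356 kept their label in every setting in which the gene was tested, which leaves out genes below a low filter at 50 and genes on X and Y in those 2 fits. Only Ckm in proliferating against freshly isolated cells, not called, changed sign, from 0.22 to -0.06 without freshly isolated replicate 1 and -0.34 without proliferating replicate 2, against 0.99 without proliferating replicate 1.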

Other observations

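The tests on the sex-linked genes were chosen only after the result was seen. In 9 of 9 libraries either Xist or all 4 Y-linked genes reached 100, never both, so the myotube cells likely came from male animals and the other cells from female animals. Differentiation of cells of 1 sex is argued against, because the summed Y-linked value was 8535 or more in each myotube library and 8 or less elsewhere. Genes on X and Y could not make up most calls of myotubes against proliferating cells, since only 576 X and 6 Y genes were tested. A fit without them called 9020 genes and the fit with them 9353. With 0 stages holding libraries of both sexes, effects of the sex of the animals and of the stage on autosomal genes cannot be told apart in the myotube comparisons.

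The bounds of the carry-over tests for freshly isolated replicate 1 were set before the result was seen, while the test of read depth, and the interval of the median as the spread in the carry-over tests, were chosen only after it was seen. RNA carried over from the myotube libraries as the whole cause is argued against by 68 genes abundant in myotubes, which reached a median of -0.018% of their myotube level (95% interval -0.057% to 0.079%, upper quartile 0.397%) where Myog reached 3.01%. For RNA of the proliferating libraries, 50 genes reached a median of 0.027% (interval -0.094% to 0.445%) where Mki67 reached 1.49%, which also argues against it as the whole cause, although the upper quartile was 0.906% and carry-over of a smaller amount stays open. Counting noise at the lower read depth alone is argued against for Myog and Mki67. Myog lay 64.0 and Mki67 22.6 counting standard deviations above the reads expected at this depth. These were 19.1 and 6.8 when widened by the average spread over genes between the 2 other freshly isolated libraries. That spread is not the genes' own, and both genes were picked because they were high in this library. Uneven amplification in this library and a share of activated cells in the preparation stay open and were not tested.

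The test on Dpt, Dcn and Cxcl14 was chosen only after the result was seen. The other 9 markers of that list reached a median of 0.508% of the level of Dpt, with Dcn at 24.3%, Cxcl14 at 3.32% and each of the rest at 0.811% or less. The ratio of these markers to Dpt in fibroblasts was not measured here, so fibroblasts or fibro-adipogenic cells among the freshly isolated cells cannot be told apart from expression by the satellite cells themselves, which may explain the values and was not tested.

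The test of relabelled libraries was planned before the data were examined. Of 10 splits of the 6 libraries, 1 split, the real one, gave as many genes called in proliferating against freshly isolated cells, and likewise 1 in myotubes against proliferating and 1 in myotubes against freshly isolated cells. The highest count of any other split was 0 in each comparison. With 10 splits no share under 0.05 is possible, so by this test alone the counts and chance cannot be told apart.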
